A study of Mus musculus with 6 samples.

How the data were processed

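RNA was taken from 6 mouse primary cortical neuronal cultures, 3 treated with NGPF2 at 1.5 ng/ml and 3 with vehicle for 2 h, and poly(A) RNA was selected, fragmented, ligated to adapters and amplified, per the labels' protocols. The submitters' processing notes name FastQC, STAR 2.5, Cuffnorm, DESeq 1.22.1 and the mm10 build, with no role or order. The annotation, the counting tool and the strand setting are not given in the sources used here, so that overlapping and antisense genes and near-identical copies were treated as uncertain.

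The deposited table is named as FPKM, but its values are log2 of a normalized count plus 1. After 2 was raised to the value and 1 subtracted, 100% of the values in each library were whole multiples of 1 step (tolerance 0.01 of a count), whatever the gene. The inverse of the step was 1.55, 1.12 and 0.838 in vehicle 1, 2 and 3, and 1.56, 0.836 and 0.557 in NGPF2 1, 2 and 3. Each equals the median-of-ratios size factor computed from the whole numbers. Whole counts were thus recovered, and totals ran from 17478070 to 45193691 per library. The plan, made before the data were examined, assumed FPKM with a pseudocount of 1 and a mean of at least 1. Because the values are normalized counts, the deposited log2 values were tested as they stand (pseudocount 1) and genes were kept at a mean normalized count of at least 10, a minimum set before any test was run. The minimum of 50 took the place of the planned stricter FPKM filter. Of 31245 genes in the table, none at 0 in all libraries, 16653 were kept. A symbol was found for 31185 identifiers and not for 60. The fold of a gene with low counts is understated on this scale. Counting intervals and floors cover counting error only.

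The columns of replicates 2 and 3 of both groups carry the library names in the sample titles. The remaining column of each group was taken as replicate 1 by elimination and by its initial, although it carries the digit 3. The fit without the block does not depend on that number. The library names of replicates 2 and 3 of both groups share a stem that the titles of replicate 1 lack. Replicates 2 and 3 were therefore taken as 1 batch and replicate 1 of both groups as another, which the titles do not state.

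Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with the replicate number as a block, empirical Bayes with a mean-variance trend, 2-sided, Benjamini-Hochberg adjustment over the genes kept, threshold 0.05). The block follows the series' statement of 3 pairs from 3 independent experiments. As a check, the deviations from the group means correlated between same-numbered libraries at r = 0.59, 0.30 and 0.33 for replicates 1, 2 and 3, and at 0.34 and 0.32 for replicates 2 and 3 crossed, across genes. Gene lists were fixed before the data were examined, 22 of pathways and 10 of cell type markers. They were tested with limma's camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. Of the 32 lists, 31 had at least 3 genes kept, and the red blood cell markers had fewer. Named genes were chosen by a rule fixed before the data were examined. It took 12 genes per direction, by size among genes that passed and otherwise by smallest p among genes moving the same way in all pairs, leaving out unnamed and clone-named genes, microRNA and snoRNA genes. It added up to 4 genes of smallest p per list and the 11 genes Arc, Fos, Egr1, Npas4, Bdnf, Gria1, Gria2, Limk1, Cfl1, Alk and Mdk. Gm47308, Gm43720, Rab11a, Gpc2 and Gfap were added after their values were seen.

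Because replicate 1 stood apart, 2 further fits were added after the data were seen. 1 used replicates 2 and 3 only, without a block (2 libraries per group). The other tested whether the effect differed between these and replicate 1, with the batch in the model. Rose and fell in replicates 2 and 3 refer to an adjusted p under 0.05 in the first of these fits. Alternatives covered the pseudocount, the filter, the block, the scaling, the variance prior and leaving out each pair, and, added after the data were seen, voom on recovered counts, computed FPKM, library totals and the batch as block. Coordinates, exon overlap and untranslated regions come from GENCODE M21, on the same build, with bedtools 2.31.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

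The test was tried on simulated data for the comparison of NGPF2 and vehicle over 3 pairs (16653 genes, 200 changed, in 4 sets of 50). With each gene's residual SD over the 3 pairs, 8% of the genes changed 4-fold and 0% of those changed 2-fold, 1.5-fold or 1.25-fold were recovered. With the residual SD within the groups of replicates 2 and 3, 52%, 30%, 8% and 0% were recovered at 4-fold, 2-fold, 1.5-fold and 1.25-fold. No unchanged gene was called in either. Of 20 further simulated lists of 25 genes shifted by 0.3 (log2), 20 were recovered in both settings and 0 of 20 unshifted lists were called. The simulated genes varied independently of each other, so this trial says nothing about lists whose genes move together. It used the preset correlation only. The correlation estimated from the data was 0.986 for the astrocyte markers.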

Results

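Messenger RNA was sequenced from 6 mouse primary cortical cultures, prepared from pups of postnatal day 1 and used after 12 to 13 days in vitro. 3 cultures were exposed to NGPF2 at 1.5 ng/ml for 2 h and 3 to vehicle (PBS) for the same time. According to the series, the cultures form 3 pairs of vehicle and NGPF2 from 3 independent experiments, and a pair here joins the vehicle and NGPF2 cultures of the same replicate number. The total count was 44788235, 32914352 and 24311967 in vehicle replicates 1, 2 and 3, and 45193691, 27105565 and 17478070 in NGPF2 replicates 1, 2 and 3. The library names set replicate 1 of both groups apart from replicates 2 and 3, so that each comparison is given for the 3 pairs and then within these batches. Values are normalized counts (count divided by the size factor of the library), and log2 differences are of the normalized count plus 1.

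The comparison of NGPF2 with vehicle asked which transcripts differed after 2 h of exposure. No gene reached an adjusted p of 0.05 over the 3 pairs. Among the 12 genes per direction of smallest p that moved the same way in each pair were, on the higher side, Faim2, an inhibitor of Fas-mediated cell death, Ppp3cb, a catalytic subunit of calcineurin, and Lrrtm4 and Rims1, a postsynaptic adhesion protein and an active zone scaffold. Faim2 (ENSMUSG00000023011, chromosome 15, 99497012 to 99528165, mm10) stood at 4407 ± 1491 normalized counts with NGPF2 and 2343 ± 583 with vehicle (SD, n = 3 each). Ppp3cb (ENSMUSG00000021816, chromosome 14, 20499364 to 20546573) stood at 14127 ± 4286 and 6111 ± 617. Among the 12 on the lower side were Mboat2, a lysophospholipid acyltransferase (ENSMUSG00000020646, chromosome 12, 24830879 to 24964397), at 1022 ± 116 and 2120 ± 261, Cbln2, a secreted organizer of synapses, at 339 ± 63.1 and 610 ± 107, and Foxm1, a transcription factor of cycling cells, at 46.7 ± 11.2 and 133 ± 32.7.

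The log2 differences of these genes over the 3 pairs were 0.88 (SE 0.10) for Faim2, 1.16 (SE 0.16) for Ppp3cb, 1.16 (SE 0.17) for Lrrtm4, 0.53 (SE 0.09) for Rims1, -1.05 (SE 0.14) for Mboat2, -0.84 (SE 0.15) for Cbln2 and -1.49 (SE 0.27) for Foxm1. The adjusted p was 0.379 for each of them (limma). The other higher genes named by the same rule were Zfp469, Cbll1, Wdr13, Gramd1b, Fstl5, Ptk2b, Brsk2 and Fam169b, and the other lower ones were Lpo, Fam107b, Mxd4, Gnpda1, Aldh1a1, Tfdp2, Syt17, Calu and Pex11a. The log2 difference ranged from 0.52 to 2.68 over the 12 higher genes and from -1.55 to -0.46 over the 12 lower genes. Unadjusted p ran from 0.000249 to 0.00228 and from 0.000549 to 0.00456. The 24 genes were chosen for moving the same way in each pair, and each differed by at least 0.395 in pair 1, where the median absolute deviation was 0.0851 over genes with a mean normalized count of at least 1000. Many of the 24, such as Foxm1, lie below that count, so this spread does not cover them. Over all genes kept, the SD of the pair 1 difference was 0.43. None of the 24 passed (adjusted p = 0.379 for each), and 10 of the 12 higher and 11 of the 12 lower genes passed in replicates 2 and 3 alone, the exceptions being Wdr13, Gramd1b and Syt17. With limma, 0 of 16653 genes passed over the 3 pairs, the smallest adjusted p being 0.0713, and 2166 genes had an unadjusted p under 0.05 where 833 were expected by chance. With voom on the recovered counts 0 passed and 1353 had an unadjusted p under 0.05. Exchanging the labels of pair 1 gave 2080 genes with an unadjusted p under 0.05 (limma). The excess therefore does not show an effect shared by the 3 pairs. Splits that part only pair 2, only pair 3 or only pair 1 gave 1263, 1215 and 126 such genes. With the replicate block each of these rests on the difference of that pair alone, so they are no comparison free of the treatment. Without replicate 1, 3275 genes passed.

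Replicates 2 and 3 differed widely between the groups and replicate 1 hardly did. Within replicates 2 and 3 (2 libraries against 2, limma), 3511 genes passed, 1627 higher and 1884 lower with NGPF2. These calls, and each gene said to rise or fall in replicates 2 and 3, take these replicates as independent. No deviation shared by replicate number was seen between the groups (r = -0.0146 across genes), and if they were repeats of 1 experiment, n would be 1 per group and no test could be made. Gfap, the intermediate filament of astrocytes, fell from 9219 and 9265 normalized counts with vehicle to 312 and 267 with NGPF2, while vehicle 1 and NGPF2 1 held 2914 and 3029. Camk2a, a kinase of excitatory synapses, rose from 53272 and 47771 to 85540 and 75417, and replicate 1 held 12518 and 13081. The SD over genes of the log2 difference was 0.43 in pair 1, 0.92 in pair 2 and 0.97 in pair 3, and 405, 2564 and 2650 genes differed by more than 2-fold.

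Across genes, which are not independent replicates, the log2 differences of pairs 2 and 3 correlated at r = 0.56, whereas those of pair 1 and the mean of pairs 2 and 3 gave r = -0.002. Of the genes that passed in replicates 2 and 3, 50.0% of the higher ones were also higher in pair 1 and 51.5% of the lower ones were also lower there. The effect itself differed between replicates 2 and 3 and replicate 1 for 415 genes, 120 with a more positive and 295 with a more negative difference in replicates 2 and 3 (limma, interaction with the library batch), and for 526 with the replicate block. Replicate 1 holds 1 library per group, so no test can be made within it, and these counts take its spread to be that between replicates 2 and 3, with the limit on their independence given above. The groups by list are therefore described with the values of each pair. Of the 31 lists 18 passed camera over the 3 pairs at its preset correlation and 21 within replicates 2 and 3, and 0 passed in either with an estimated correlation. The fits leave 2 residual degrees of freedom, so the test with an estimated correlation has little power. Over the 3 pairs it gave the same adjusted p of 0.481 to the astrocyte markers and to the NMDA, kainate and metabotropic receptors. A list that did not pass it is therefore not shown to be unchanged.

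**Figure D1:**
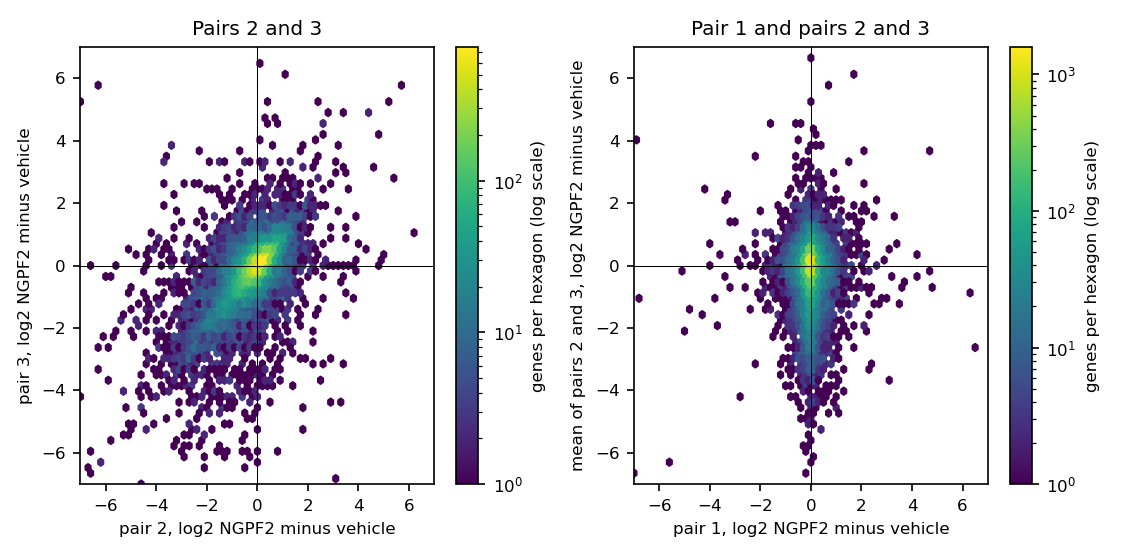
Log2 difference (NGPF2 minus vehicle) of 16653 genes, in pair 2 against pair 3 (left) and in pair 1 against the mean of pairs 2 and 3 (right), colour giving genes per hexagon on a log scale and genes beyond 7 in either direction not drawn. The cloud runs along the diagonal on the left (r = 0.56) and along the vertical axis on the right (r = -0.002).

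Markers of astrocytes, microglia, oligodendrocyte precursors and fibroblast and mural cells were far lower with NGPF2 in replicates 2 and 3 and near equal in pair 1, and those of oligodendrocytes and endothelial cells were not. All 14 measured astrocyte markers fell in replicates 2 and 3, among them Gfap (31.9-fold), Aldoc, a glycolytic aldolase (8.71-fold), Gja1, the gap junction protein connexin 43 (8.44-fold), and Fgfr3 (9.87-fold). The median log2 difference of the astrocyte markers was 0.02 in pair 1, -2.81 in pair 2 and -2.81 in pair 3. Of 13 microglia markers 10 fell, including C1qb, a complement subunit (12.4-fold), and Laptm5 (4.43-fold), and the pair medians were 0.13, -2.50 and -2.19. The fold of C1qb rests on few counts, at 3.59 and 8.97 normalized counts in NGPF2 2 and 3. Of 7 markers of oligodendrocyte precursors 4 fell, including the transcription factors Olig1 (5.52-fold) and Olig2 (6.06-fold), with medians of 0.02, -1.46 and -1.37.

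Of 13 fibroblast and mural cell markers 6 fell and 1 rose in replicates 2 and 3, with medians of -0.12, -2.14 and -1.75 in pairs 1 to 3. Collagen Col3a1 fell 3.61-fold and the receptor Pdgfrb 9.55-fold, the latter to 10.8 and 5.38 normalized counts in NGPF2 2 and 3. Of 12 neural progenitor markers 6 fell, among them Vim (3.22-fold) and Fabp7 (4.51-fold), with medians of 0.01, -0.78 and -0.91. Adjusted over the list alone, 14 astrocyte markers, 11 microglia markers, 4 precursor markers, 8 fibroblast and mural markers and 7 progenitor markers fell in replicates 2 and 3. Over the 3 pairs no marker passed when adjusted over all genes, and 13 astrocyte markers passed adjusted over the list alone. As a list, the astrocyte markers were lower over the 3 pairs with camera at its preset correlation (adjusted p = 3.01e-07), as were those of microglia (7.85e-06), fibroblast and mural cells (0.000356) and oligodendrocyte precursors (0.00618). None passed with an estimated correlation, a test of little power here, where each of these 4 had an adjusted p = 0.481. The progenitor markers did not pass over the 3 pairs (adjusted p = 0.0601, and adjusted p = 0.488 with an estimated correlation) and passed as lower within replicates 2 and 3 (adjusted p = 0.0155, and adjusted p = 0.243 with an estimated correlation). Markers of oligodendrocytes (0.05, -0.30 and -0.15 in pairs 1 to 3) and of endothelial cells (0.08, -0.34 and -0.35) did not pass (adjusted p = 0.214 and adjusted p = 0.294). In replicates 2 and 3, 1 of 10 oligodendrocyte markers rose and 2 fell, and 1 of 6 endothelial markers fell, as they did adjusted over the list alone.

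**Figure D2:**
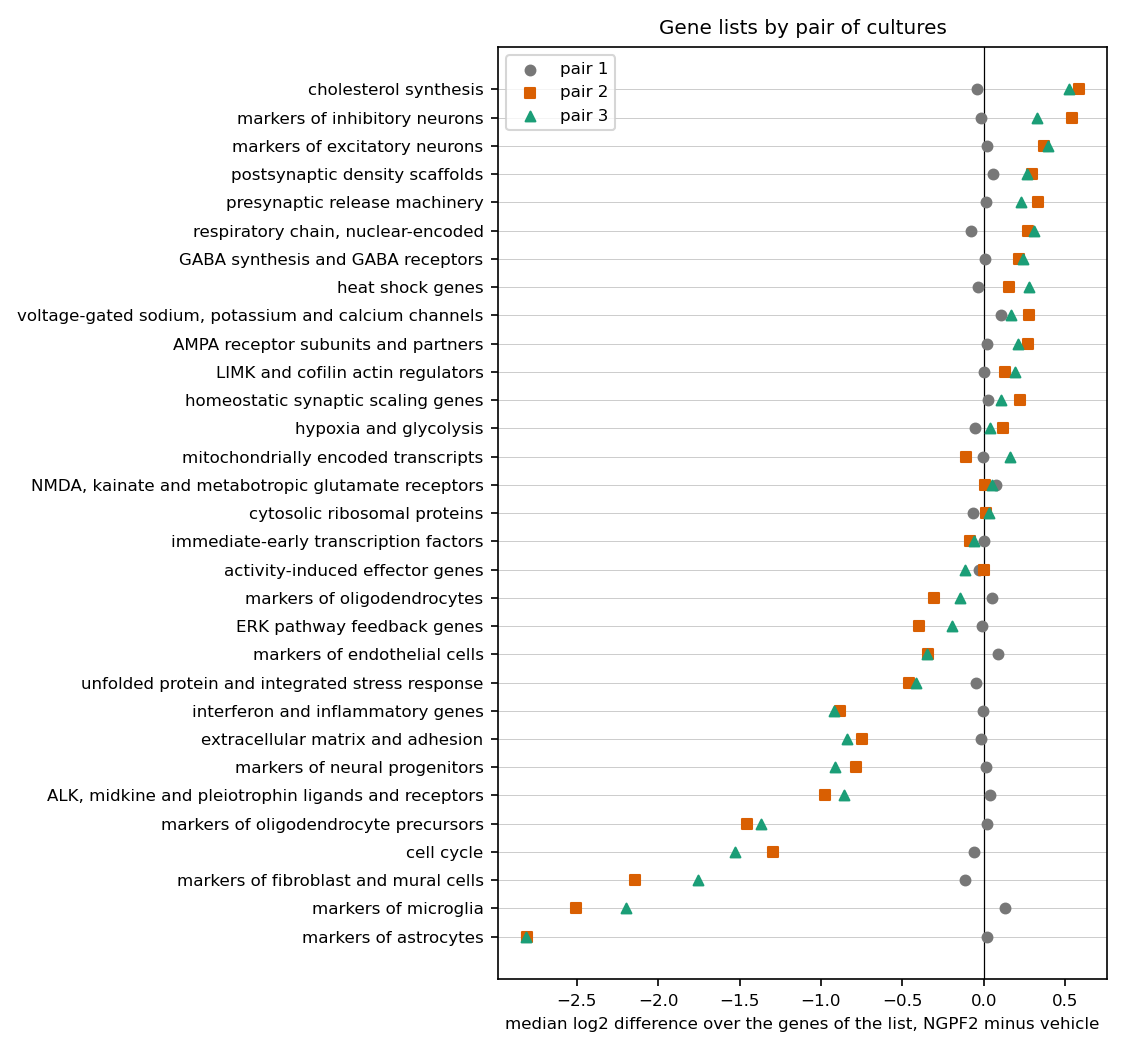
Median log2 difference (NGPF2 minus vehicle) over the measured genes of each of 31 gene lists, with 1 point per pair of cultures. Pairs 2 and 3 lie near each other from -2.81 for the astrocyte markers to 0.59 for cholesterol synthesis, and the pair 1 medians lie within 0.131 of 0.

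Lists of dividing and non-neuronal cells and of stress went the same way as these markers. Of 26 cell cycle genes 16 fell in replicates 2 and 3 (19, and 1 higher, adjusted over the list alone), including the cyclin Ccna2 (6.05-fold) and the kinase Cdk1 (4.10-fold). The medians of the cell cycle list were -0.06, -1.30 and -1.53 in pairs 1 to 3. Of 29 extracellular matrix and adhesion genes 13 fell and 2 rose (15 and 3 adjusted over the list alone), Sparc by 4.30-fold and the fibronectin gene Fn1 by 3.30-fold. Of 23 interferon and inflammatory genes 7 fell (7, and 1 higher, adjusted over the list alone), among them Icam1 (9.84-fold, to 13.2 and 3.59 normalized counts in NGPF2 2 and 3) and Ifit3 (3.51-fold). Of 27 genes of the unfolded protein and integrated stress response 14 fell and 1 rose (16 and 1 adjusted over the list alone), including Chac1 (2.90-fold) and Sesn2 (2.29-fold). Medians in pairs 1 to 3 were -0.02, -0.75 and -0.84 for the matrix list, -0.01, -0.88 and -0.92 for the interferon list and -0.05, -0.46 and -0.42 for the stress list. Over the 3 pairs, camera with the preset correlation gave an adjusted p of 8.18e-07 for the cell cycle, 0.000134 for matrix, 0.00132 for interferon and 0.000216 for stress genes. With an estimated correlation none passed, each with an adjusted p = 0.481. The astrocyte markers, 2.81 lower in both pairs 2 and 3, moved with these lists.

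Synaptic lists moved by less and upwards, in the same 2 pairs in which the median astrocyte marker was 2.81 lower. Of 29 postsynaptic density genes 13 rose and 1 fell in replicates 2 and 3 (14 and 2 adjusted over the list alone), among them the scaffolds Dlgap3 (1.86-fold) and Shank3 (1.56-fold). Of 30 genes of presynaptic release 13 rose and 1 fell (17 and 4 adjusted over the list alone), including Cplx2 (1.54-fold) and Rims1 (1.46-fold). Of 30 AMPA receptor subunits and partners 9 rose and 1 fell (11 and 1 adjusted over the list alone), the auxiliary subunits Gsg1l by 2.28-fold and Cacng3 by 1.99-fold. Gria1 rose 1.30-fold in replicates 2 and 3. Gria2 stood at 13896 ± 1529 normalized counts with NGPF2 and 13692 ± 3527 with vehicle (SD, n = 3), a difference whose sign changed with quantile and library total scaling. Of 20 GABA genes 9 rose and 4 fell (12 and 4 adjusted over the list alone), the receptor subunit Gabrd by 2.80-fold.

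Of 32 voltage-gated channels 8 rose and 4 fell in replicates 2 and 3 (13 and 4 adjusted over the list alone), among them Kcnc1 and Cacna1h (1.49-fold), and of 25 homeostatic scaling genes 9 rose and 4 fell (10 and 4 adjusted over the list alone). The medians in pairs 1 to 3 were 0.06, 0.29 and 0.27 for the postsynaptic list, 0.01, 0.33 and 0.23 for the presynaptic, 0.02, 0.27 and 0.21 for the AMPA, 0.01, 0.22 and 0.24 for the GABA, 0.10, 0.28 and 0.17 for the channel and 0.03, 0.22 and 0.11 for the scaling list. Over the 3 pairs these 6 lists passed camera at the preset correlation, with adjusted p of 6.94e-05, 0.000314, 0.000216, 0.0304, 0.000126 and 0.0385 in that order. None passed with an estimated correlation (adjusted p = 0.481 for each). Over the 3 pairs, 1 gene of the postsynaptic list (Lrrtm4) and 1 of the presynaptic list (Rims1) passed adjusted over the list alone and 0 passed over all genes. The NMDA, kainate and metabotropic receptor list did not pass (adjusted p = 0.204), with medians of 0.07, 0.01 and 0.05, and 4 of its 21 genes rose and 1 fell in replicates 2 and 3 (4 and 1 adjusted over the list alone), Grin1 by 1.50-fold.

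Among lists of neuronal identity, markers of inhibitory neurons passed at the preset correlation (adjusted p = 0.00941, and adjusted p = 0.481 with an estimated correlation) and those of excitatory neurons did not (adjusted p = 0.0926). Their medians in pairs 1 to 3 were -0.02, 0.54 and 0.33 and 0.02, 0.37 and 0.40, where those of astrocytes, microglia and mural cells were -2.81, -2.50 and -2.14 in pair 2. Members went both ways in replicates 2 and 3. The transcription factors Lhx6 and Neurod2 rose 1.82-fold and 1.98-fold, while the neuropeptides Sst and Npy fell 2.11-fold and 2.79-fold. Of 15 inhibitory markers 8 rose and 3 fell (11 and 3 adjusted over the list alone), and of 14 excitatory markers 7 rose and 4 fell (9 and 4).

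Of 23 cholesterol synthesis genes 17 rose in replicates 2 and 3 and none fell (19 adjusted over the list alone). Mvk, mevalonate kinase, rose 1.94-fold, Sqle, squalene epoxidase, 1.67-fold and Hmgcs1 1.52-fold, and the medians of the list were -0.04, 0.59 and 0.52 in pairs 1 to 3. Of 45 nuclear-encoded genes of the respiratory chain 19 rose and none fell (28 adjusted over the list alone), Cox5a by 1.58-fold, with medians of -0.08, 0.27 and 0.31. Over the 3 pairs the adjusted p was 1.46e-06 for cholesterol synthesis and 5.76e-06 for the respiratory chain at the preset correlation. With an estimated correlation neither passed (adjusted p = 0.481 and adjusted p = 0.513). In pairs 2 and 3, where these lists were higher, the astrocyte markers were lower, and in pair 1 the medians of these 3 lists lay within 0.08 of 0. The heat shock list did not pass over the 3 pairs (adjusted p = 0.0601) and passed as higher within replicates 2 and 3 (adjusted p = 0.0122, and adjusted p = 0.243 with an estimated correlation), with medians of -0.04, 0.15 and 0.28, and 9 of its 20 genes rose and 2 fell in replicates 2 and 3 (10 and 2 adjusted over the list alone), Hsph1 by 1.42-fold. The lists of hypoxia and glycolysis (medians of -0.06, 0.11 and 0.04 in pairs 1 to 3), mitochondrially encoded transcripts (-0.01, -0.11 and 0.16) and cytosolic ribosomal proteins (-0.06, 0.01 and 0.03) had adjusted p of 0.986, 0.908 and 0.732, the last 2 lower at an adjusted p under 0.05 with quantile scaling. In replicates 2 and 3, 9 of 26 hypoxia and glycolysis genes rose and 4 fell (10 and 7 adjusted over the list alone), 0 of 13 mitochondrial transcripts passed, and 1 of 75 ribosomal protein genes rose (0 adjusted over the list alone). The median of the hypoxia and glycolysis list over the 3 pairs (-0.00) and its test (higher) differed in sign.

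Activity-regulated genes did not move as a group. The immediate-early transcription factors had medians of 0.00, -0.08 and -0.06 in pairs 1 to 3 (adjusted p = 0.86) and the activity-induced effector genes -0.03, -0.00 and -0.11 (adjusted p = 0.811). In replicates 2 and 3 members went both ways. Egr3 rose 2.14-fold, Ier5 2.01-fold and Arc, an immediate-early gene of synaptic plasticity, 1.45-fold, while Fos fell 1.56-fold, Egr1 1.24-fold, Bdnf, the brain-derived neurotrophic factor, 1.43-fold and Scg2, a granin of secretory vesicles, 2.95-fold. Of 26 immediate-early factors 5 rose and 7 fell (5 and 10 adjusted over the list alone), and of 36 effector genes 11 rose and 8 fell (11 and 13). Npas4, an activity-dependent transcription factor, stood at 1441 ± 713 normalized counts with NGPF2 and 1433 ± 628 with vehicle (SD, n = 3). The log2 differences over the 3 pairs were 0.37 (SE 0.14) for Arc, -0.47 (SE 0.14) for Fos and -0.41 (SE 0.11) for Bdnf, with limma's adjusted p = 0.379 for each. Of 23 ERK feedback genes 4 rose and 8 fell in replicates 2 and 3 (4 and 9 adjusted over the list alone), Dusp1 by 2.36-fold and Etv5 by 1.67-fold. The ERK list did not pass over the 3 pairs (adjusted p = 0.084), with medians of -0.01, -0.40 and -0.19. These changes in single genes came in the 2 pairs in which the median astrocyte marker was 2.81 lower.

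Genes of ALK signalling and of actin regulation by LIM kinase and cofilin were among the lists. Of 18 genes of the list of ALK, midkine and pleiotrophin ligands and receptors 9 fell in replicates 2 and 3 (12 lower and 2 higher adjusted over the list alone). The medians were 0.04, -0.97 and -0.86 in pairs 1 to 3. The list was lower over the 3 pairs at the preset correlation (adjusted p = 0.000995), and not with an estimated one (adjusted p = 0.481 with an estimated correlation). The median astrocyte marker was 2.81 lower in the same 2 pairs. The members that fell included Ptprz1, a receptor phosphatase abundant in glia (8.22-fold), Alkal2, an ALK ligand (5.92-fold), and the midkine gene Mdk (3.72-fold). Alk itself stood at 271 ± 258 normalized counts with NGPF2 and 268 ± 236 with vehicle (SD, n = 3), a log2 difference of -0.03 (SE 0.24). That difference changed sign with quantile scaling.

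Of 30 LIMK and cofilin regulators 8 rose and 2 fell in replicates 2 and 3 (10 and 2 adjusted over the list alone). Limk1, the LIM kinase gene, rose 1.90-fold, the cofilin gene Cfl1 1.43-fold, Actg1 1.64-fold and Wasf1 1.65-fold, and Rock2 fell 1.72-fold. Limk1 held 1383 and 1351 normalized counts in vehicle 2 and 3 and 2772 and 2423 in NGPF2 2 and 3, against 2449 and 2566 in the vehicle and NGPF2 cultures of replicate 1. The list did not pass over the 3 pairs (adjusted p = 0.0542, and adjusted p = 0.481 with an estimated correlation), with medians of 0.00, 0.13 and 0.19. It passed as higher within replicates 2 and 3 (adjusted p = 0.0164, and adjusted p = 0.243 with an estimated correlation). In pairs 2 and 3 the median astrocyte marker was 2.81 lower.

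**Figure D3:**
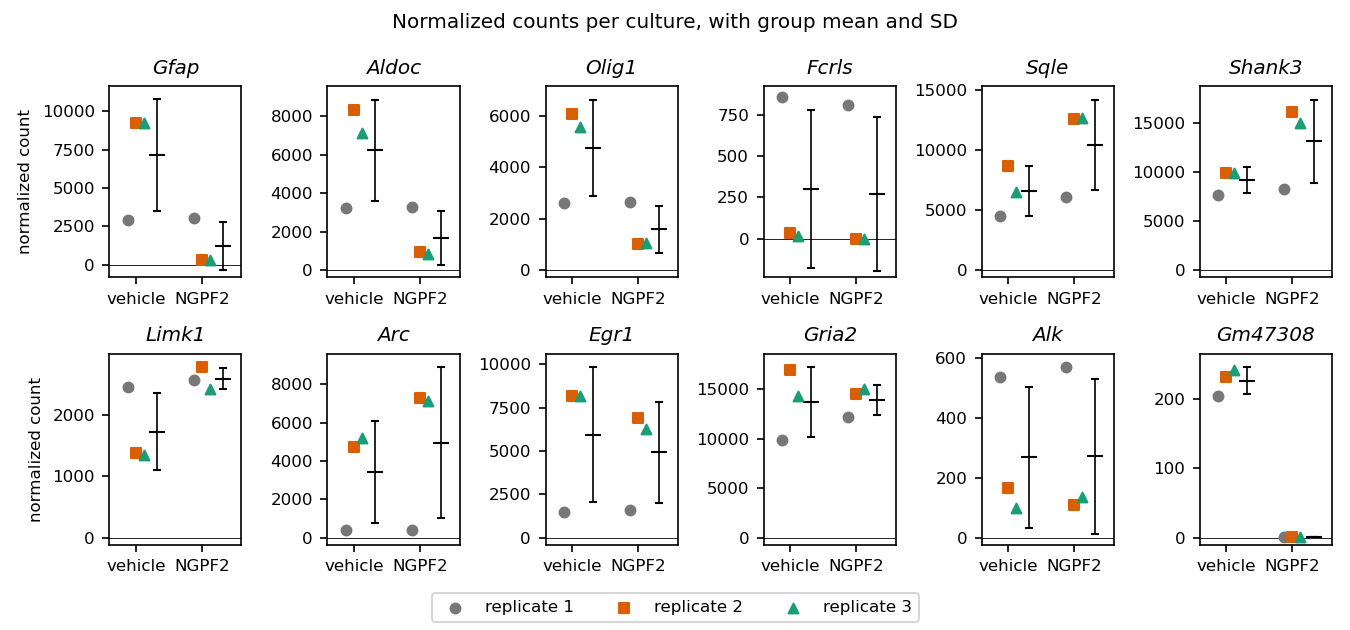
Normalized counts of 12 genes in each of the 6 cultures, by group, with symbols for the replicate number and the group mean and SD (n = 3) in black. Replicates 2 and 3 differ between the groups for Gfap, from 9219 and 9265 to 312 and 267, while replicate 1 holds 2914 and 3029, and Gm47308 is near 0 in all 3 NGPF2 cultures.

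The transcripts with the largest differences in all 3 pairs were chosen after their values were seen. Gm47308, a microRNA gene of 107 bases (ENSMUSG00000104953, chromosome 9, 64726624 to 64726730, minus strand, inside an exon of Rab11a), had 317, 259 and 203 counts in the vehicle libraries and 1 count in each NGPF2 library. That is a ratio of 219 (95% exact counting interval 74.6 to 1063). The interval does not cover a drop of a single gene in 1 library. Another gene, picked after the values were seen, held 1566 normalized counts in vehicle 1, 0.6 in NGPF2 1 and from 1440 to 1521 in the other libraries. Gm47308 had the smallest adjusted p over the 3 pairs (limma, 0.0713), and passed without the replicate block (0.0141). Rab11a (chromosome 9, 64715299 to 64737758) stood at 4454 ± 111 normalized counts with NGPF2 and 4402 ± 203 with vehicle (SD, n = 3), a difference whose sign changed with quantile and library total scaling. Gm43720 (ENSMUSG00000106247, chromosome 5, 138264952 to 138279958), which overlaps Gpc2 and Gal3st4 on the same strand, had 76, 101 and 53 counts with vehicle and 0 in each NGPF2 library. With a floor of 3 counts set for the NGPF2 group it was 64.6-fold lower (limma, adjusted p = 0.379), and the lower limit of its 95% exact counting interval was 52.1. A gene table does not separate the reads of overlapping genes, so both values are uncertain.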

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

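The tests of the difference between replicates 2 and 3 and replicate 1, and all tests of explanations here except those of read depth and of 3' untranslated regions and the counts over splits, were chosen after the results were seen. In groups of 3 no single library was tested as an outlier.

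For 415 genes the difference between NGPF2 and vehicle was not the same in replicates 2 and 3 as in replicate 1 (limma, interaction with the library batch). Replicate 1 holds 1 library per group, so this test of genes and lists assumes that its libraries vary as replicates 2 and 3 do, and the spread between these is that of repeats if they come from 1 experiment. Of the 31 lists, 20 differed with camera at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.264). The median of the interaction (replicates 2 and 3 minus replicate 1) was -2.77 for markers of astrocytes, -2.64 for microglia, -1.75 for fibroblast and mural cells, -1.31 for oligodendrocyte precursors and -0.73 for neural progenitors. It was -1.27 for the cell cycle, -0.87 for ALK, midkine and pleiotrophin genes, -0.83 for interferon genes, -0.68 for extracellular matrix and -0.55 for the stress response. It was 0.57 for cholesterol synthesis, 0.46 for markers of inhibitory neurons, 0.40 for the respiratory chain, 0.33 for postsynaptic scaffolds, 0.27 for presynaptic release, 0.24 for heat shock genes, 0.23 for GABA genes, 0.20 for LIMK and cofilin regulators, 0.20 for AMPA receptor genes and 0.0873 for ribosomal proteins.

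Of the genes named here, 24 had an adjusted p under 0.05 in the same test, on the same assumption. The interaction was -5.05 for Gfap, -3.14 for Aldoc, -3.02 for Gja1, -2.94 for Fgfr3, -2.17 for Laptm5, -1.80 for Col3a1, -2.49 for Olig1, -2.62 for Olig2, -2.62 for Ccna2, -2.05 for Sparc, -1.08 for Sesn2, -2.53 for Alkal2, -3.09 for Ptprz1, -1.02 for Sst, -1.06 for Dusp1, -0.72 for Etv5 and -2.21 for Fabp7. It was 1.00 for Mvk, 0.82 for Dlgap3, 1.01 for Gsg1l, 1.05 for Cacng3, 1.34 for Gabrd, 1.06 for Ier5 and 0.97 for Neurod2.

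Markers of astrocytes, microglia, oligodendrocyte precursors and fibroblast and mural cells, but not those of oligodendrocytes and endothelial cells, were far lower in NGPF2 replicates 2 and 3 than in their vehicle cultures. A response to NGPF2 common to the 3 experiments is argued against by pair 1, whose median astrocyte marker differed by 0.0212 (median absolute deviation 0.0682 over the markers). Read depth is argued against as well, since with every library thinned to 17478070 counts the median in pairs 2 and 3 was still -2.76. Fewer of these cells and lower expression in them cannot be told apart, since both would give the 85.7% of the 14 astrocyte markers that were lower by more than 1 in both pairs, and if transcription had stopped at the start of the 2 h, the median marker would need a half-life of 43.1 min and Gfap, the astrocyte marker that fell most, 24.0 min. Whether such a difference was there before the treatment or came with it stays open, because in replicates 2 and 3 it coincides with the group, and a response of these experiments alone to NGPF2 stays open as well.

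The second pattern was that single genes differed in steps between libraries that were otherwise near-identical. Of 5813 genes with a mean normalized count of at least 1000, 161 differed by more than 0.5 (log2) in pair 1, such as Epm2aip1 (1301 and 8054 normalized counts in vehicle 1 and NGPF2 1), where the median absolute deviation was 0.0851. Such genes also differed by more than 0.5 between vehicle 2 and 3 14.6 times as often as the other genes (26.1% and 1.79%), which may point to counting that is unstable for particular genes (34.2% of the 161 moved in pairs 2 and 3 as in pair 1), and their longest annotated 3' untranslated region was longer by 851 bases in the median (2598 and 1747, permutation p = 1e-05, the smallest 100000 resamples can give). Exons shared on the same strand, in the annotation used here, are argued against as the main cause. Of the 161, 9.32% shared at least 10% of their exon bases with another gene on their strand (2.44% of the others). Overlap with genes on the opposite strand was not measured. Since the strand setting of the counting is not known, such overlap stays open as a cause. The 24 genes named over the 3 pairs, each different by at least 0.395 in pair 1, stay open to unstable counting. For Gm43720, whose NGPF2 libraries were at 0, the summed count of Gm43720, Gpc2 and Gal3st4 differed by a mean of -0.155 (log2, SD 0.425, n = 3 pairs). A sum near equal would follow if its reads were given to the genes it overlaps. The sum is a weak test, since Gpc2 held 169, 33.9 and 51.3 normalized counts of the sums of 219, 125 and 119 in vehicle 1, 2 and 3. Loss of Gm43720 alone would thus lower the sum only in part, and the question stays open. The values hold no such test for Gm47308.

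The third pattern was that replicates 2 and 3 of a group were far closer to each other than to the same-numbered culture of the other group. The median chi-square over genes was 2.18 for vehicle 2 and 3, 2.96 for NGPF2 2 and 3 and 2.08 for vehicle 1 and NGPF2 1, against 0.455 for sampling alone, with depths not matched, and 16.1 and 9.83 for vehicle and NGPF2 of replicates 2 and 3. If replicates 2 and 3 were experiments with deviations shared by both groups, vehicle 2 minus 3 and NGPF2 2 minus 3 would correlate, and across genes they did so at r = -0.0146, which argues against such shared deviations. If replicates 2 and 3 were repeats of 1 experiment, the calls within them would rest on the spread between repeats, with n = 1 per group. No biological explanation was tested for this pattern.

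The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest of the others 1. With a real count of 0 all 10 splits give as many by construction, so that this comparison says nothing about chance. For lists, 2 of the 10 splits gave as many as the real split, which gave 18, and the highest other was 19. That other split exchanged the labels of pair 1 and kept those of replicates 2 and 3. The remaining splits that part all 3 pairs gave 3 and 0 lists. With the replicate block, each of the 6 splits that part 1 pair only rests on the difference between NGPF2 and vehicle in that pair. Those that part pair 2 gave 17 and 17 lists, those that part pair 3 gave 15 and 15, and those that part pair 1 gave 3 and 3. These 6 splits are thus no comparison free of the treatment, and they hold no contrast of the library batch. Within replicates 2 and 3, the split by treatment called 3511 genes and the other 2 splits 0 and 0.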

How the results depend on the processing

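Voom, computed FPKM, library totals, the library batch and replicates 2 and 3 alone were chosen after the data were seen, and the other alternatives before. The count of 0 genes stayed at 0 with pseudocounts of 0.1 and 0.25, without a filter, at a mean count of at least 50, with median-of-ratios, quantile and library total scaling, with the robust prior and with voom. With no replicate block 1 gene passed (Gm47308), with the experiment as a random effect and no fixed block 2, with a mean computed FPKM of at least 1 and the replicate block 1, and with the library batch as block 1. The cause was not tested. Leaving out 1 pair gave 0 to 3275 genes, the highest without replicate 1, and replicates 2 and 3 alone 3511. Pair 1 thus decides whether many genes pass or none.

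Of the lists, 18 passed, and 15 to 21 in the alternatives at the preset correlation (18 to 21 when 1 pair was left out). With the correlation estimated 0 passed, and 0 with fry and the replicate block. Over the lists and alternatives, 467 results kept direction and side of the threshold, 22 passed that had not, 19 no longer passed and 17 changed direction. For the named genes 1319 kept both, 169 passed that had not and 13 changed direction. Quantile scaling called 5 lists higher and 12 lower where the deposited scaling called 9 and 9. Library totals moved the median of all genes to -0.09.

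Values near 0 changed direction. By list median, hypoxia and glycolysis gave -0.00675 with no filter and the replicate block, -0.00406 with no replicate block, -0.00406 with the experiment as a random effect and no fixed replicate block, -0.0732 with quantile normalisation and -0.0891 with library totals as scaling (-0.0501 to 0.0633 when 1 replicate was left out). Mitochondrially encoded transcripts gave -0.172 with quantile normalisation (adjusted p = 0.00146, in a range over the alternatives up to 0.981), 0.0277 with a mean computed FPKM of at least 1, -0.0574 with library totals as scaling, and -0.0572 to 0.0829 when 1 replicate was left out. Activity-induced effector genes gave -0.139 with library totals as scaling and -0.0726 in replicates 2 and 3 only (-0.0950 to -0.0141 when 1 replicate was left out). Cytosolic ribosomal proteins passed as lower with quantile normalisation (adjusted p = 0.000145, in a range up to 0.891) and with library totals as scaling, and gave 0.0223 in replicates 2 and 3 only (-0.0281 to 0.0223 when 1 was left out), and immediate-early transcription factors -0.0691 to -0.0520 when 1 was left out. The direction of a list is that of its test, so that a median could keep its sign.

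Alk gave 0.187 with quantile normalisation and 0.00127 with voom on the recovered counts (-0.262 to 0.262 when 1 replicate was left out). Gria2 gave -0.0715 with quantile normalisation, -0.0354 with library totals as scaling and -0.0731 in replicates 2 and 3 only. Rab11a gave -0.0520, -0.0675 and -0.00644 in the same 3 settings, and Npas4 0.0454 in replicates 2 and 3 only. When 1 replicate was left out, Gria2 ran from -0.0731 to 0.186, Rab11a from -0.00644 to 0.0442 and Npas4 from -0.108 to 0.0454. The shallowest library held 17478070 counts, and low genes such as Fam169b rest on few of them.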

Other observations

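The vehicle cultures of replicates 2 and 3 differed from that of replicate 1, which is a single library, so these are values without a test. Single activity-regulated genes stood higher in vehicle 2 and 3, while the lists went both ways, with a median log2 difference from vehicle 1 of 0.31 (SD over genes 1.27) for the immediate-early factors and 0.26 (SD 1.29) for the effector genes. Arc was at 4739 and 5213 normalized counts against 394, Egr1 at 8196 and 8199 against 1461, Bdnf at 5921 and 6653 against 2813 and Npas4 at 1754 and 1836 against 710. Fos did not follow, at 1774 and 1867 against 2379.

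The interneuron peptide gene Sst was at 2998 and 3286 normalized counts in vehicle 2 and 3 against 21131 in vehicle 1, and Gria1 at 11590 and 10533 against 21996. The median log2 difference of vehicle 2 and 3 from vehicle 1 was 1.14 for astrocyte markers (SD over genes 0.66), -1.20 for microglia markers (SD 2.30), -1.82 for fibroblast and mural markers (SD 1.27) and -1.35 for markers of inhibitory neurons (SD 0.97). The astrocyte markers of vehicle 1 and NGPF2 1 thus lay between those of the vehicle and the NGPF2 cultures of replicates 2 and 3, as for Gfap at 2914 and 3029. PC1 held 55.3% of the variance, with replicate 1 at -73.9 and -74.3, vehicle 2 and 3 at 0.80 and 3.40 and NGPF2 2 and 3 at 67.5 and 76.5.

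In each library odd numbers made up a share of the counts from 1 to 9 from 64.4% to 65.6%, against 49.1% to 50.2% of the counts of at least 1000.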
